A study of Homo sapiens with 12 samples.

How the data were processed

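Poly(A)-selected messenger RNA was sequenced in 12 libraries of MDA-MB-231, a human triple-negative breast cancer cell line, held for 24 h in culture medium of 3 acidities. Each of the groups, pH 7.4, pH 6.9 and pH 6.4, had 4 libraries numbered as repeats in the labels. Per the labels' protocols, 500000 cells were plated in flasks, reached 70 to 80% confluence at pH 7.4 and were then moved to medium of the set pH. The sample labels call the intermediate medium pH 6.9, while the protocol and design text give pH 6.7 for it. The name pH 6.9 is used throughout, and which value is right is not given in the sources used here. The word repeat does not state separate cultures, so every p-value below measures only the spread between these samples.

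The deposited values were raw counts of reads per gene, 1 table for all 12 libraries. Libraries were made with a stranded kit for poly(A) RNA and sequenced on a NextSeq500, per the labels' protocols. Reads were aligned with STAR to GRCh38.p13 (hg38) and counted with featureCounts, per the submitters' processing notes. Versions, the strand setting and the treatment of reads that map to several places are not given in the sources used here. Values of genes that overlap a neighbour, lie antisense to one or have near-identical copies are therefore uncertain. Among the named genes, another annotated gene overlaps ACAT2, ALPP, AQP1, AQP5, ASNS, ATF5, CA9, CAV1, CCN2, CCNB2, CD44, CDH1, CDKN1A, COL1A2, DDIT3, DHCR7, DUSP6, ERBB3, ESR2, FBN1, FEN1, GARS1, GNL3, GRAMD1C, HK2, HMMR, IER3, IFIT1, ISG15, ITGA5, KDR, KRT8, LAMA3, LDHA, LINC00882, LPIN1 and LSS. The same holds for LUCAT1, MCL1, MCOLN1, ME1, MIF, MMP1, MTHFD2, MVK, MX1, NDUFV2, NFAT5, NPC1, OAS3, PCK2, PHLDA1, PPARA, PPARGC1A, RAB17, RAB3B, RELN, RPSAP52, S100A4, SLC4A2, SLC4A7, SLC5A3, SLC6A12, SLC6A6, SLC7A11, SLC9A7, SMAD3, TIMP1, TMSB4XP8, TNC, UBE2S, ULK1, VEGFA and WNK4. Pseudogene copies by symbol exist for others, namely AKR1B1, ATF4, BUB1, DNAJA1, PKM, PSAT1, RPL3, RPL39, RPL7A, RPS16, SLC2A3 and XBP1, and KRTAP2-3, AOC2 and AOC3 have paralogs. The table held 60664 genes, of which 60463 matched the table of gene symbols and 58396 matched GENCODE release 29, the source of the coordinates and gene types. Genes without a symbol took at most 0.424% of the counts of any library. None of the 66 pairs of libraries were copies of each other, since at least 17212 genes differed in count within every pair.

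Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Low counts were removed with filterByExpr, which left 17544 genes, and libraries were scaled with TMM. A model with 1 term per medium was fitted to all 12 libraries with 9 residual degrees of freedom, and edgeR's robust quasi-likelihood test compared pH 6.4 with pH 7.4, pH 6.9 with pH 7.4 and pH 6.4 with pH 6.9. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Every adjusted p given for a gene comes from this test unless another tool is named. CPM values are counts scaled to a common library total after TMM, with their SD over the 4 libraries of a group. The common biological coefficient of variation was 0.198.

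Lists of genes for 32 processes, with 1008 symbols that all matched the table, were tested with limma's camera at a preset correlation of 0.01, adjusted over the 32 lists. The same test with a correlation estimated per list, and limma's fry, were run beside it. Camera compares a list with all other genes, while fry asks whether a list's own genes move one way. Adjusted p-values for lists come from camera with the preset correlation unless stated otherwise. For each list the count of called genes is also given adjusted over the list alone. A list needed at least 5 tested members.

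The lists, the named genes' rule, the main test and the first set of alternatives were chosen before the data were examined. The rule named the 8 largest rises and 8 largest falls per comparison among called genes with a mean of at least 5 CPM in the higher group, an official symbol and no overlap between the groups' libraries. It also named up to 4 called members per list, or up to 2 members as values where none was called. Some genes and 1 list are not reported here. A gene named for 1 comparison could be given in the others. Markers of 4 cell types foreign to the line or to its basal state were fixed in the same way.

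The test was tried on simulated counts with the real means and library sizes and a set of altered genes among 17180. For pH 6.4 against pH 7.4 it recovered 40.3% of 67 genes altered 1.5-fold, 64.2% of 67 altered 2-fold and 86.4% of 66 altered 4-fold, and called 0.0294% of unaltered genes. For pH 6.4 against pH 6.9 the shares were 43.3%, 61.2% and 83.3%, with 0.0353% of unaltered genes called. All 3 list methods recovered the 1 list altered 1.5-fold, and fry called 1 other list. The simulated genes were drawn independently of each other, with no structure among the repeats. In the real data the estimated correlation was 0.64 for the replication list at pH 6.9 against pH 7.4. The trial therefore does not show how the tests behave on correlated genes. Counts ranged from 21060767 to 50643233 per library.

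Alternatives covered other scaling, no filter and a stricter filter on low counts, DESeq2, a fit of only the groups compared, the repeat number as a block, each library left out in turn, a stricter threshold and a minimum fold change of 1.5. After the data were seen, the libraries of repeats 1 and 2 were found to differ from those of repeats 3 and 4 in every medium, and 3 libraries stood apart. Fits within each pair of repeats, fits with that split as a term, fits without those libraries and DESeq2 within each pair were therefore added. Values within repeats 1 and 2 and within repeats 3 and 4 are given for some genes and lists beside the pooled ones. Comparisons against the same pH 7.4 libraries share their chance values, so the overlap of both acid media was set against 20 simulations of unchanged groups and against 6 splits of the pH 7.4 libraries into pairs. The library composition was compared between media with exact 2-sided permutation tests of the difference in means. All columns of the count table were used.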

Results

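The data set measured messenger RNA in MDA-MB-231 breast cancer cells kept for 24 h in medium of pH 7.4, pH 6.9 or pH 6.4, with 4 libraries per medium. Its title asks, among other things, how acidity and hypoxia bear on the spread of cancer cells. Total counts were 33746080, 47644714, 21060767 and 43973921 in the pH 7.4 libraries, 49684807, 49803831, 27018171 and 37176449 at pH 6.9, and 41719869, 50643233, 41766622 and 31118831 at pH 6.4, in the order of repeats 1 to 4. Repeat 1 at pH 7.4 held 17841 detected genes and repeat 2 at pH 6.9 held 21628, while the other 10 libraries held from 23113 to 27384. The first principal component took 40.6% of the variance and set that pH 7.4 library, at -144.67, apart from the others, which lay between -7.24 and 36.39. The second component, with 25%, ran from the pH 7.4 libraries other than repeat 1 to the pH 6.4 libraries, and the third, with 12.3%, parted repeats 1 and 2 from repeats 3 and 4 in each medium.

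Each library was placed on an axis over abundant genes that was fitted without it, from 0 at the mean of the other pH 7.4 libraries to 1 at the mean of the other pH 6.4 libraries. The pH 7.4 libraries lay between -0.00374 and 0.0948, the pH 6.9 libraries between 0.229 and 0.391, and 3 pH 6.4 libraries between 0.894 and 1.3. Repeat 3 at pH 6.4 lay at 0.493, between the media. Total counts, detected genes and 4 shares of the counts were compared between the media in 18 exact permutation tests, and none passed after adjustment. With 4 libraries per group a single difference could not pass among 18 tests, so this does not show equal composition. The lowest p was 0.0571 (adjusted p = 0.514), where the smallest possible was 0.0286, for the mitochondrial ribosomal RNA MT-RNR2. It took 1.348% ± 0.258 of counts at pH 6.4, 0.981% ± 0.164 at pH 7.4 and 0.909% ± 0.128 at pH 6.9 (SD, n = 4). The p-value was the same for pH 6.4 against either medium.

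**Figure D1:**
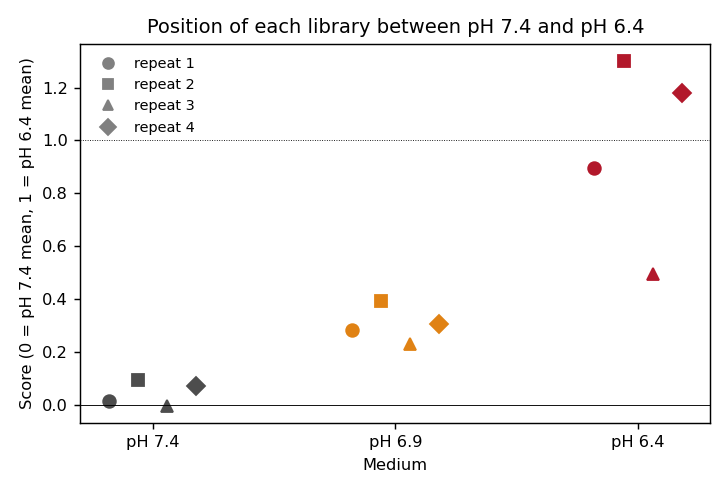
Score of each library on an axis over abundant genes, without unit, where 0 is the mean of the pH 7.4 libraries and 1 that of the pH 6.4 libraries, each without the library placed. Each symbol is 1 library and its shape gives the repeat, and repeat 3 at pH 6.4 (0.493) lies between the pH 6.9 libraries and the other pH 6.4 libraries.

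At pH 6.4 the growth factor gene AREG, 5 of 6 targets of the glucose-sensing factor MondoA, led by TXNIP, and 21 of 29 stress response genes rose. Of the cholesterol genes 20 of 25 fell, as did the aldose reductase gene AKR1B1 and 24 of 40 replication genes, while 25 of 40 mitosis genes rose. None of these 5 lists passed with an estimated correlation, with adjusted p = 0.245 for MondoA targets, adjusted p = 0.162 for the stress response and cholesterol, adjusted p = 0.713 for replication and adjusted p = 0.451 for mitosis. Of the genes named by rule the serine protease homologue PRSS35 fell the most.

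This comparison asked which genes respond to the more acid medium. In pH 6.4 against pH 7.4, 2737 genes were higher and 2584 lower of 17544 tested, which is 30.3%. Of these, 505 rises and 751 falls had an estimate over 2-fold, and the median size of a called change was 0.61 on the log2 scale. Tested against a fold change of 1.5, 281 genes were higher and 315 lower. The groups' libraries did not overlap for 4900 genes (27.9%), where chance gives 2.86% on average over all splits of the same libraries. Genes move together, so a single split can lie far from that average, and its spread was not measured. With library size in place of TMM scaling, the share of higher genes among the calls was 40.4% in place of 51.4%.

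Among 27 acid-base transporters, 5 rose and 6 fell (7 and 9 adjusted over the list alone), and the list did not pass (adjusted p = 0.702). Its mean change was above 0 while its median and the test pointed down. The anion exchanger SLC4A2, which exports bicarbonate, fell from 308 to 150.1 CPM (log2 -1.04, adjusted p = 0.000108). The bicarbonate importer SLC4A7 rose by 1.15 and the organellar exchanger SLC9A7 by 1.24 on the log2 scale. Of 9 proton sensors and acid-gated channels 3 rose and 2 fell (4 and 2 adjusted over the list alone; adjusted p = 0.337, and 0.000844 by fry). The acid-activated chloride channel gene PACC1 rose by 0.88, whereas the acid-sensing ion channel ASIC1 changed by -1.27 and the potassium channel KCNK2 by -1.28.

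MondoA targets rose in 5 of 6 cases, with none lower (5 and 0 adjusted over the list alone; adjusted p = 0.000215, and adjusted p = 0.245 with an estimated correlation). TXNIP (ENSG00000265972, chromosome 1 from 145992435 to 145996600), which restrains glucose uptake, had 172 ± 55.4 CPM at pH 7.4 and 1180 ± 538.9 at pH 6.4 (SD, n = 4), a 6.86-fold rise (log2 2.78, SE 0.34; adjusted p = 8.06e-05). Its log2 change was 2.77 within repeats 1 and 2 and 2.82 within repeats 3 and 4. The related arrestin ARRDC4 rose by 2.12 and the hexokinase HK2 by 0.57. Glycolysis as a list did not pass (adjusted p = 0.702; 4 of 23 rose and 2 fell, the same counts adjusted over the list alone), and abundant PKM and LDHA, which end the pathway, fell by 0.57 and 0.66 while the glucose transporter SLC2A3 rose by 1.08. Hypoxia targets outside glycolysis did not pass either (adjusted p = 0.275), with 5 of 25 higher and 1 lower (5 and 1 adjusted over the list alone), and VEGFA, which drives vessel growth, rose from 272 to 481 CPM. The hypoxia list passed upward within repeats 3 and 4 (adjusted p = 0.0308) and not within repeats 1 and 2 (0.755).

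Genes of the amino acid and integrated stress response rose in 21 of 29 cases (22 adjusted over the list alone), and 1, ATF5, which was named after its value was seen, fell by 0.77 (list mean 0.84, adjusted p = 7.44e-13, and adjusted p = 0.162 with an estimated correlation). The glutathione-degrading enzyme CHAC1 rose 4.05-fold, from 2.55 ± 0.543 to 10.5 ± 2.63 CPM (SD, n = 4). The mitochondrial folate enzyme MTHFD2 rose by 1.20 (adjusted p = 3e-05), the glycyl-tRNA synthetase GARS1 by 1.02, the regulator ATF4 by 0.62 and its partners DDIT3 and TRIB3 by 0.87 and 1.17. The asparagine synthetase ASNS rose by 3.17 from under 1 CPM, a value that is uncertain because another transcript on its strand covers it. Of 26 NRF2 targets, 9 rose and 5 fell (9 and 6 adjusted over the list alone; adjusted p = 0.702). Among them the cystine importer SLC7A11 rose by 1.48 and the steroid reductase AKR1C1 fell by 1.68.

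Cholesterol synthesis and uptake fell in 20 of 25 genes and rose in none (21 and 0 adjusted over the list alone; list mean -0.68, adjusted p = 6.73e-17, and adjusted p = 0.162 with an estimated correlation). The mevalonate kinase MVK fell 2.26-fold from 50.9 ± 4.48 to 22.5 ± 2.33 CPM (SD, n = 4; log2 -1.17, SE 0.10; adjusted p = 5.93e-06), by -1.27 within repeats 1 and 2 and -1.07 within repeats 3 and 4. The thiolase ACAT2 and the lanosterol synthase LSS fell by 1.19 and 1.13. Fatty acid synthesis fell in 10 of 20 genes and rose in 3 (11 and 3 adjusted over the list alone; adjusted p = 2.63e-05, and adjusted p = 0.162 with an estimated correlation), among them the malic enzyme ME1 with -1.03 and the phosphatidate phosphatase LPIN1 with -0.90. Fatty acid oxidation and lipid droplet genes did not pass (adjusted p = 0.702; 5 of 27 rose and 2 fell, the same counts adjusted over the list alone). Their regulator PPARGC1A nevertheless went from 12.6 to 1.89 CPM and PPARA, another regulator, rose by 1.21.

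Replication and G1/S genes fell in 24 of 40 cases and 1, E2F7, rose (26 and 1 adjusted over the list alone; list mean -0.46, adjusted p = 4.67e-08, and adjusted p = 0.713 with an estimated correlation). The origin-licensing factor CDC6 fell from 131 to 72.7 CPM, the cyclin CCNE1 by 0.89, and the helicase subunit MCM6 and the flap nuclease FEN1 by 0.48 each. Mitosis genes rose in 25 of 40 cases and 1, HMMR, which was named after its value was seen, fell by 0.76 (28 and 1 adjusted over the list alone; list mean 0.32, adjusted p = 1.96e-07, and adjusted p = 0.451 with an estimated correlation). The checkpoint kinase BUB1, the securin PTTG1 and the cyclin CCNB2 rose by 0.82, 0.67 and 0.59. Growth arrest genes rose in 8 of 24 cases and fell in 2 (the same counts adjusted over the list alone; adjusted p = 0.114, and 0.0203 by fry), with GADD45A at 0.82 and CDKN1A at 0.58. Apoptosis genes gave 8 rises and 2 falls of 24 (9 and 3 adjusted over the list alone; adjusted p = 0.285, and 0.0367 by fry), and both the death-promoting BBC3 and the survival gene MCL1 rose, by 1.29 and 0.69. Replication-dependent histones, of which 16 of 44 were tested, gave 1 fall, H4C8 (1 adjusted over the list alone; adjusted p = 0.702).

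**Figure D2:**
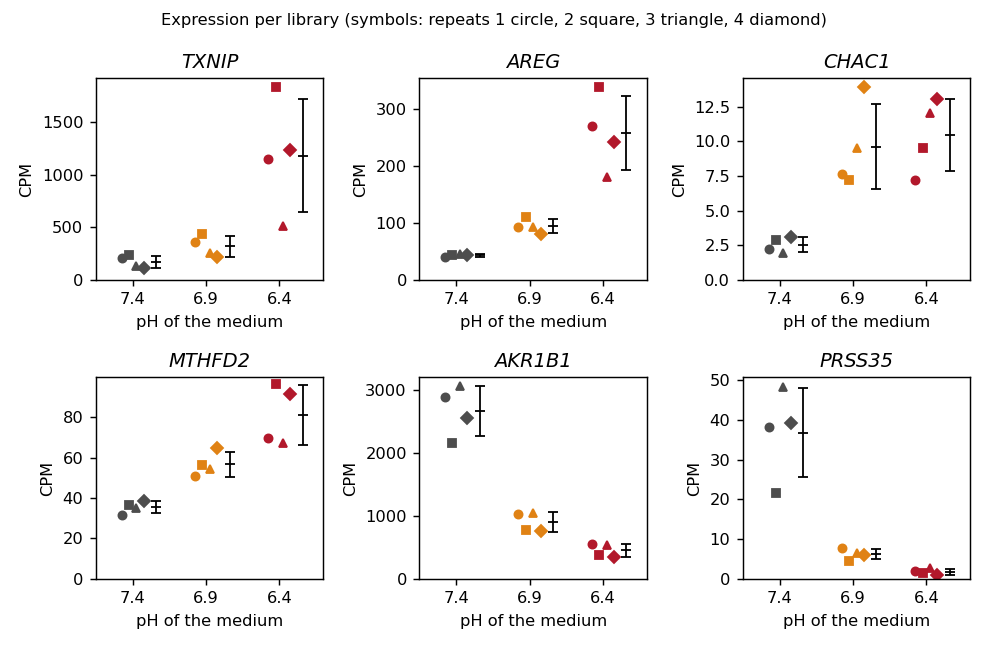
CPM values of 6 genes in the 12 libraries, by pH of the medium, with each axis starting at 0. Symbols are single libraries with the shape giving the repeat, black marks give the mean and SD of 4 libraries, and TXNIP goes from a mean of 172 to 1180 CPM while AKR1B1 goes from 2662 to 454.2.

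Immediate early and MAPK response genes rose in 16 of 30 cases and fell in 2 (18 and 2 adjusted over the list alone; list mean 0.57, adjusted p = 2.64e-07, and adjusted p = 0.245 with an estimated correlation). AREG (ENSG00000109321, chromosome 4 from 74445134 to 74455009), a ligand of the epidermal growth factor receptor, rose 5.97-fold from 43.2 ± 2.86 to 258 ± 65.7 CPM (SD, n = 4; log2 2.58, SE 0.16; adjusted p = 4.32e-07). Within repeats 1 and 2 it changed by 2.87 and within repeats 3 and 4 by 2.26. PHLDA1, MYC and the ERK phosphatase gene DUSP6 rose by 0.93, 0.85 and 0.68. Inflammatory cytokines and NF-kB genes did not pass (adjusted p = 0.0553; 10 of 32 rose and 3 fell, 12 and 3 adjusted over the list alone), with RELB up by 0.90 and the inhibitor NFKBIA down. They passed upward within repeats 3 and 4 (adjusted p = 0.000157) and with the repeat number as a block (0.0125), and not within repeats 1 and 2 (0.104). Interferon response genes fell in 12 of 35 cases and rose in 2 (the same counts adjusted over the list alone; adjusted p = 0.00954, adjusted p = 0.759 with an estimated correlation and adjusted p = 0.0786 by fry). The antiviral genes ISG15, MX1 and OAS3 changed by -0.98, -1.13 and -1.10. This list passed within repeats 1 and 2 (adjusted p = 0.00297) but not within repeats 3 and 4 (0.107), and it did not pass without repeat 1 at pH 7.4 (0.0571) or without the 2 libraries with the fewest genes (0.0788).

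Genes of water and volume regulation went both ways, with 7 of 28 higher and 7 lower (the same counts adjusted over the list alone; adjusted p = 0.702, with the mean and the test down and the median up). AKR1B1 (ENSG00000085662, chromosome 7 from 134442350 to 134459284), which makes the osmolyte sorbitol, fell 5.86-fold from 2662 ± 400.7 to 454.2 ± 103.8 CPM (SD, n = 4; log2 -2.55, SE 0.17; adjusted p = 8.99e-07), by -2.42 within repeats 1 and 2 and -2.66 within repeats 3 and 4. The inositol transporter SLC5A3 went from 890 to 326 CPM, although the gene MRPS6 shares its strand and place. The taurine transporter SLC6A6 rose from 148 to 276 CPM. The water channel AQP5 fell from 10.2 to 1.40 CPM.

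PRSS35 (ENSG00000146250, chromosome 6 from 83512538 to 83525704) fell 21.6-fold, from 36.8 ± 11.1 to 1.67 ± 0.762 CPM (SD, n = 4; log2 -4.44, SE 0.32; adjusted p = 1.11e-06). The other large falls among genes named by rule were the non-coding LINC00882 (-3.77), the growth factor binding protein FGFBP1 (-3.75), the prostaglandin-degrading HPGD (-3.39), the trafficking GTPase RAB17 (-3.29), the phosphatase ALPP (-2.99) and the tight junction protein CGN (-2.91). The largest rises under that rule were KRTAP2-3 (3.94), the kinase WNK4 (3.63), AOC3 (3.03), OVGP1 (2.91), RPSAP52 (2.85), TXNIP, the cytokine IL24 (2.75) and NDUFV2 (2.63). Reads of KRTAP2-3, ALPP, AOC3, RPSAP52, WNK4, NDUFV2 and LINC00882 could belong in part to paralogous, overlapping or antisense genes, so these values are uncertain. Of these rises all but TXNIP were larger within repeats 1 and 2 than within repeats 3 and 4, with KRTAP2-3 at 4.70 and 3.50, WNK4 at 4.13 and 3.20, AOC3 at 4.04 and 2.05, OVGP1 at 3.35 and 2.41, RPSAP52 at 3.28 and 2.48, IL24 at 3.67 and 1.82 and NDUFV2 at 3.53 and 1.68.

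Matrix and matrix proteolysis genes went both ways, with 13 of 42 higher and 13 lower (16 and 13 adjusted over the list alone; adjusted p = 0.702). The membrane protease MMP14 rose from 330 to 763 CPM and the metalloprotease inhibitor TIMP1 by 0.83. The matrix glycoprotein TNC fell from 229 to 101 CPM (log2 -1.18, adjusted p = 2.13e-06) and the fibrillin FBN1 by 1.02. Adhesion and integrin genes rose in 12 of 44 cases and fell in 5 (the same counts adjusted over the list alone; adjusted p = 0.244, and 0.0123 by fry). The fibronectin receptor chain ITGA5, the hyaluronan receptor CD44 and the laminin LAMA3 rose by 1.02, 0.87 and 1.16, and the caveolar CAV1 fell by 0.77. Epithelial-mesenchymal transition genes gave 8 rises and 6 falls of 24 (9 and 8 adjusted over the list alone; adjusted p = 0.958), with the mean and the test below 0 and the median above it. KRT8, SNAI2 and S100A4 fell by 0.74, 0.82 and 0.88. TGF-beta response genes gave 7 rises and 7 falls of 27 (9 and 7 adjusted over the list alone; adjusted p = 0.757), with the mean below 0 and the median and the test above it, the signal carrier SMAD3 at 1.06 and the ligand BMP4 at -1.32. YAP and TEAD targets gave 9 rises and 2 falls of 29 (10 and 2 adjusted over the list alone; adjusted p = 0.114), among them the matricellular CCN2 at 1.06.

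Heat shock genes fell in 5 of 17 cases (6 adjusted over the list alone; adjusted p = 0.0111, and adjusted p = 0.689 with an estimated correlation). The co-chaperone HSPH1 fell from 479 to 182 CPM (log2 -1.40, adjusted p = 8.48e-07) and DNAJA1 by 0.55. That list passed within repeats 3 and 4 (adjusted p = 0.000651) but not within repeats 1 and 2 (0.138), and it did not pass without repeat 3 at pH 6.4 (0.135). Endoplasmic reticulum chaperone genes gave 8 rises and 1 fall of 20 (9 and 2 adjusted over the list alone; adjusted p = 0.105), with the unfolded protein factor XBP1 at 0.89. Lysosome and autophagy genes gave 6 rises and 17 falls of 47 (the same counts adjusted over the list alone; adjusted p = 0.0748), with the calcium channel MCOLN1 at -1.14, the pump subunit ATP6V0D1 at -0.89 and the sterol transporter NPC1 at 0.89. This list passed downward within repeats 1 and 2 (adjusted p = 0.0291) and with the block (0.0277), and not within repeats 3 and 4 (0.138). Cytosolic ribosomal proteins rose in 6 of 58 cases (2 adjusted over the list alone; list mean 0.13, adjusted p = 0.0287, adjusted p = 0.83 with an estimated correlation and adjusted p = 0.125 by fry), RPL3 by 0.31. The list was past the threshold within repeats 3 and 4 (adjusted p = 1.2e-05) but not within repeats 1 and 2 (0.227), with library size only (0.153), with the stricter filter (0.0639), or without repeat 3 (0.12) or repeat 4 (0.185) at pH 7.4 or repeat 2 at pH 6.4 (0.0566). Ribosome biogenesis and MYC targets gave 4 rises and 5 falls of 32 (3 and 5 adjusted over the list alone; adjusted p = 0.702). Nuclear genes of oxidative phosphorylation gave 4 rises and 4 falls of 43 (3 and 3 adjusted over the list alone; adjusted p = 0.609). For the 13 mitochondrially encoded mRNAs no call was made (adjusted p = 0.975; none adjusted over the list alone).

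Camera put 10 of the 32 lists past the threshold, 5 in each direction, and fry 12. With an estimated correlation none passed, although 5 had an unadjusted p under 0.05. Of the 10 lists, interferon and ribosomal proteins did not pass by fry. The 7 lists other than interferon, heat shock and ribosomal proteins passed within both pairs of repeats, replication with an adjusted p of 2.45e-14 in repeats 1 and 2 and 0.00025 in repeats 3 and 4. Such a pass can be weak evidence. For replication, 7 of 35 splits of the same libraries, the real one included, gave a camera p-value as small as the real one. For the stress response, fatty acid synthesis and MAPK lists only the real split did. Of all 5321 genes called in the pooled fit, 66.3% were also called within repeats 1 and 2 and 26.8% within repeats 3 and 4. Of the 130 calls named by rule, 5 and 31 were lost there. Of 73 called genes chosen for the text, 13 were not called within repeats 3 and 4, namely AOC3 (adjusted p = 0.11), NDUFV2 (0.0739), AQP5 (0.0571), SLC4A7 (0.0963), RPL3 (0.0932), ERN1 (0.173), SNAI2 (0.058), HK2 (0.0675), LDHA (0.0965), SLC2A3 (0.0765), ISG15 (0.0822), IFIT1 (0.0943) and GNL3 (0.131). All 73 had the same direction within both pairs of repeats as in the pooled fit. These genes were chosen by their values in the same libraries, the largest changes only where the groups' libraries did not overlap. The shared direction was therefore largely fixed beforehand and is no independent evidence. All cells were meant to be of 1 line. Fibroblast markers fell in 5 of 6 tested cases, among them COL1A2 with -1.20 and LUM with -1.93, at no more than 54.3 CPM. Of the leukocyte markers 1 of 4 fell (CD14, -1.07), of the endothelial markers 1 of 3 rose (KDR, 0.91), and of the luminal markers CDH1 (-1.76) and KRT8 fell and ERBB3 (0.81) rose, of 6 tested. Leukocyte and endothelial markers reached at most 10.6 and 12.4 CPM, but luminal markers reached 973. At pH 7.4 KRT8 had a mean of 885 CPM and CDH1 1.77.

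**Figure D3:**
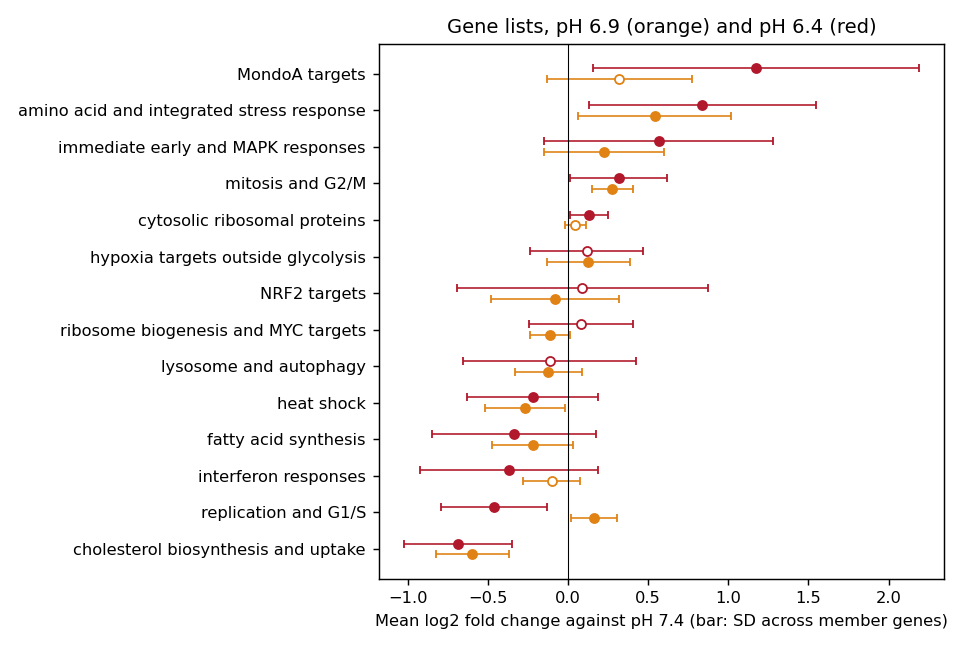
Mean log2 fold change of 14 gene lists that passed at pH 6.9 (orange) or pH 6.4 (red) against pH 7.4, with bars for the SD across member genes. Filled marks passed camera with a preset correlation at an adjusted p under 0.05 and open marks did not, and cholesterol synthesis has -0.60 at pH 6.9 and -0.68 at pH 6.4.

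At pH 6.9 cells already held less transcript of cholesterol synthesis genes and of the heat shock gene HSPH1, and more of the amino acid response genes CHAC1, PSAT1 and SLC1A4. AKR1B1, PRSS35 and FGFBP1 had fallen and AREG had risen. TXNIP, which rose at pH 6.4, did not pass.

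This comparison asked what milder acidity does. In pH 6.9 against pH 7.4, 55 genes were higher and 72 lower (0.724% of those tested), 7 and 15 of them with an estimate over 2-fold. Tested against a fold change of 1.5, 0 genes were higher and 4 lower. An unadjusted p under 0.05 was reached by 2092 genes, and DESeq2 called 275 higher and 284 lower. The libraries did not overlap for 1771 genes (10.1%), where chance gives 2.86% on average, with a spread that was not measured. The counts rested on single libraries, with 12 higher and 27 lower without repeat 3 at pH 7.4, and 154 and 152 without repeat 3 at pH 6.4. Within repeats 1 and 2 edgeR called 2 and 5 genes, and within repeats 3 and 4 none, where 1194 genes had an unadjusted p under 0.05 and DESeq2 called 52 and 69. With the repeat number as a block 519 genes were higher and 428 lower, and 28 more of the named values were called.

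CHAC1 (ENSG00000128965, chromosome 15 from 40952962 to 40956519) rose 3.72-fold to 9.6 ± 3.07 CPM (SD, n = 4; log2 1.90, adjusted p = 0.00266), by 1.54 within repeats 1 and 2 and 2.17 within repeats 3 and 4. The neutral amino acid transporter SLC1A4, the serine synthesis enzyme PSAT1 and the mitochondrial PCK2, which overlaps NRL, rose by 1.16, 1.14 and 1.06, and ATF4 by 0.54 (adjusted p = 0.00532). The stress response list had 5 rises of 29 and no falls (17 and 1 adjusted over the list alone; list mean 0.54, adjusted p = 1.63e-19, and adjusted p = 0.0501 with an estimated correlation). The sterol enzymes SC5D, DHCR7 and MVK fell by 0.84, 0.74 and 0.68. The cholesterol list had 9 falls of 25 and no rises (24 and 0 adjusted over the list alone; list mean -0.60, adjusted p = 7.6e-46, and adjusted p = 0.0231 with an estimated correlation). Fatty acid synthesis had 2 falls of 20, ME1 (-0.62) and LPIN1 (-0.44), and no rises (8 and 0 adjusted over the list alone; adjusted p = 1.24e-08, and adjusted p = 0.0328 with an estimated correlation).

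HSPH1 (ENSG00000120694, chromosome 13 from 31134974 to 31162388) fell from 479 ± 56.8 to 251.6 ± 20.6 CPM (SD, n = 4; log2 -0.93, adjusted p = 0.000923), by -0.82 within repeats 1 and 2 and -1.03 within repeats 3 and 4. The heat shock list had 2 falls of 17, HSPH1 and DNAJA1, and no rises (6 and 0 adjusted over the list alone; list mean -0.27, adjusted p = 3.16e-09, and adjusted p = 0.0741 with an estimated correlation). Mitosis genes had 4 rises of 40 and no falls (26 and 0 adjusted over the list alone; list mean 0.28, adjusted p = 6.33e-19, and adjusted p = 0.0765 with an estimated correlation), namely CDK1 (0.45), TOP2A (0.43), CCNB2 (0.41) and BIRC5 (0.40). AREG rose to 94.0 ± 12.7 CPM (SD, n = 4; log2 1.12, adjusted p = 0.00339) and DUSP6 by 0.44, and the MAPK list had these 2 rises of 30 and no falls (6 and 1 adjusted over the list alone; adjusted p = 0.000107, adjusted p = 0.4 with an estimated correlation and adjusted p = 0.119 by fry). Lysosome and autophagy genes had 2 falls of 47, NEU1 (-0.62) and MCOLN1 (-0.69), and no rises (9 and 1 adjusted over the list alone; adjusted p = 9.98e-06, adjusted p = 0.4 with an estimated correlation and adjusted p = 0.17 by fry). NRF2 targets passed downward with 1 call, ME1 (5 falls and 1 rise adjusted over the list alone; adjusted p = 0.0353, adjusted p = 0.4 with an estimated correlation and adjusted p = 0.196 by fry).

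Replication genes passed upward at pH 6.9 (list mean 0.16, adjusted p = 0.000254), hypoxia targets upward (0.13, adjusted p = 0.0353) and ribosome biogenesis downward (-0.11, adjusted p = 0.00192). None of these passed with an estimated correlation (adjusted p = 0.676, adjusted p = 0.425 and adjusted p = 0.591) or by fry (adjusted p = 0.437, adjusted p = 0.162 and adjusted p = 0.409). No single member of these lists was called by edgeR over all genes or adjusted over the list alone. The carbonic anhydrases CA9 and CA12 gave 0.94 (adjusted p = 0.114) and 0.73 (adjusted p = 0.11). TXNIP had 318.5 ± 98.9 CPM (SD, n = 4; log2 0.89, adjusted p = 0.259), and MondoA targets did not pass (adjusted p = 0.119) but did upward within repeats 1 and 2 (0.0292) and with the block (0.0364), and not within repeats 3 and 4 (0.0972). Of the water and volume genes AKR1B1 fell 2.95-fold to 901.1 ± 155.9 CPM (SD, n = 4; adjusted p = 0.000923) and SLC5A3 by 0.87 (adjusted p = 0.0416), in a list of 28 that did not pass (adjusted p = 0.0827; 3 falls adjusted over the list alone). It passed downward within repeats 3 and 4 (adjusted p = 0.00668) and with the block (0.00932), and not within repeats 1 and 2 (0.383).

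PRSS35 fell 5.95-fold to 6.18 ± 1.25 CPM (SD, n = 4; log2 -2.57, adjusted p = 0.000923). Other large falls under the naming rule were LINC00882 (-2.68), FGFBP1 (-2.20), the oestrogen receptor ESR2 (-1.48), the secreted RELN (-1.30), ALPP (-1.23) and the microtubule protein MAP2 (-1.14), and large rises included the glucocorticoid-induced factor KLF9 (0.98), GRAMD1C (0.96) and the non-coding LUCAT1 (0.93). ESR2, LUCAT1, ALPP and LINC00882 share reads or place with other genes and are uncertain. TNC fell by 0.51 and the TGF-beta decoy receptor BAMBI by 0.77. With each of the 12 libraries left out in turn, 17 of 37 named calls remained in every run, among them CHAC1, SLC1A4, AREG, ATF4, SC5D, DHCR7, MVK, ME1, HSPH1, AKR1B1, PRSS35 and FGFBP1.

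Camera put 11 lists past the threshold, 5 up and 6 down, and fry 5. The cholesterol and fatty acid synthesis lists held with an estimated correlation and the other 9 did not. Within repeats 1 and 2, ribosome biogenesis (adjusted p = 0.0578), NRF2 (0.117) and hypoxia (0.154) did not pass, and all 11 passed within repeats 3 and 4. In that last fit edgeR called no gene, so a pass there is weak evidence. Inflammatory genes (adjusted p = 0.0827) passed upward within repeats 3 and 4 (0.0033) and with the block (0.0167), ribosomal proteins (adjusted p = 0.296) upward within repeats 3 and 4 (0.00417), and histones (adjusted p = 0.0505) downward with the block (0.0402). Hypoxia targets lost the threshold without repeat 3 (adjusted p = 0.0733) or 4 (0.25) at pH 7.4 or repeat 1 at pH 6.9 (0.182), and NRF2 targets without repeat 1 (0.0622) or 2 (0.0811) at pH 7.4 or repeat 3 (0.0701) or 4 (0.0877) at pH 6.9. NRF2 targets also lost it without repeat 1 at pH 7.4 and repeat 3 at pH 6.4 (adjusted p = 0.0752).

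Both acid media were then set side by side. Of the 127 genes called at pH 6.9, 121 were also called at pH 6.4 and all of these in the same direction. They were 52 higher genes, among them AREG, CHAC1 and ATF4, where independent lists would share 8.58, and 69 lower genes, among them PRSS35, AKR1B1 and HSPH1, where independent lists would share 10.6. These counts became 12 and 27 without repeat 3 at pH 7.4, 112 and 126 without repeat 3 at pH 6.4, and 472 and 395 with the block. Across genes, which are not independent replicates, the log2 changes correlated with r = 0.666 and rho = 0.601. Both comparisons used the same pH 7.4 libraries. In 20 simulations of unchanged groups every library, those of pH 7.4 included, was drawn anew from the pH 7.4 means. The mean r of these simulations was 0.505 (0.48 to 0.518). The covariance was 0.185 against 0.0565 in the simulations, a difference of 0.129. The deviations of the real pH 7.4 libraries did not enter, so this difference does not measure their part in the correlation. When the pH 7.4 libraries were split between the comparisons in 6 ways, r ranged from 0.152 to 0.357 and the covariance from 0.0689 to 0.122, with a mean of 10.7 higher and 22.3 lower genes in both.

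**Figure D4:**
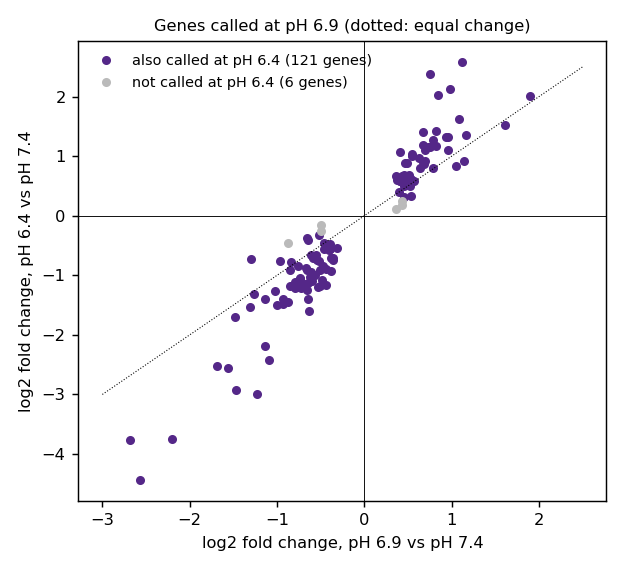
Log2 fold change at pH 6.9 (horizontal) and pH 6.4 (vertical) against pH 7.4 for the 127 genes called at pH 6.9. Each point is 1 gene, purple for the 121 also called at pH 6.4 and grey for the other 6, and the dotted line marks equal change.

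Between pH 6.9 and pH 6.4, 35 of 40 replication genes fell, in a list with adjusted p = 0.612 with an estimated correlation, while TXNIP and AREG rose. CHAC1, PSAT1 and SC5D, which had changed at pH 6.9, gave no further call.

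This comparison asked which changes separate the acid media. In pH 6.4 against pH 6.9, 1550 genes were higher and 1438 lower (17%), 183 and 256 of them with an estimate over 2-fold. Tested against a fold change of 1.5, 2 genes were higher and 1 lower. Single libraries moved these counts, to 659 and 512 without repeat 2 at pH 6.4 and to 2474 and 2470 without repeat 3 at pH 6.4, and the block gave 2823 and 2633. The libraries did not overlap for 3585 genes (20.4%), where chance gives 2.86% on average, with a spread that was not measured. With library size in place of TMM scaling, higher genes were 38.2% of the calls in place of 51.9%.

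Replication and G1/S genes fell in 35 of 40 cases and 1, E2F7, rose (37 and 1 adjusted over the list alone; list mean -0.62, adjusted p = 3.6e-23, and adjusted p = 0.612 with an estimated correlation). MCM6 had 124 ± 6.34 CPM at pH 7.4, 147.8 ± 6.58 at pH 6.9 and 88.9 ± 21.3 at pH 6.4 (SD, n = 4), a change of -0.73 between the acid media (adjusted p = 0.00415). It was -0.92 within repeats 1 and 2 and -0.54 within repeats 3 and 4. CDC6 fell by 0.79 (adjusted p = 0.00294) and FEN1, which overlaps FADS2, by 0.66. Mitosis genes did not pass (adjusted p = 0.372; 6 of 40 rose and 4 fell, the same counts adjusted over the list alone).

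MondoA targets rose in 5 of 6 cases (5 adjusted over the list alone; adjusted p = 0.000269, and adjusted p = 0.612 with an estimated correlation), with TXNIP at 1.89 (adjusted p = 0.00418; 1.90 within repeats 1 and 2 and 1.89 within repeats 3 and 4) and ARRDC4 at 1.35. MAPK response genes rose in 11 of 30 cases and fell in 2 (14 and 3 adjusted over the list alone; adjusted p = 0.000112, and adjusted p = 0.765 with an estimated correlation), with AREG at 1.45 and IER3 at 0.72. Stress response genes rose in 10 of 29 cases (12 higher and 1 lower adjusted over the list alone; adjusted p = 0.00116, adjusted p = 0.765 with an estimated correlation and adjusted p = 0.0779 by fry), with TRIB3 at 0.82, DDIT3 at 0.65 and MTHFD2 at 0.52, while CHAC1 gave 0.12 (adjusted p = 0.774). Endoplasmic reticulum chaperone genes rose in 7 of 20 cases (8 adjusted over the list alone; adjusted p = 0.0128, adjusted p = 0.804 with an estimated correlation and adjusted p = 0.31 by fry), with the stress sensor ERN1 at 1.03 and XBP1 at 0.53. Cholesterol synthesis fell in 5 of 25 cases and did not pass as a list (6 adjusted over the list alone; adjusted p = 0.137), with SC5D at 0.06.

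Ribosome biogenesis rose in 5 of 32 cases and fell in 1 (8 and 2 adjusted over the list alone; adjusted p = 0.0161, adjusted p = 0.804 with an estimated correlation and adjusted p = 0.253 by fry), with the nucleolar GNL3 at 0.59 and MYC at 0.60. Interferon response genes fell in 6 of 35 cases and rose in 1 (10 and 3 adjusted over the list alone; adjusted p = 0.0399, adjusted p = 0.804 with an estimated correlation and adjusted p = 0.316 by fry), with OAS3 at -0.94. It did not pass with library size only (adjusted p = 0.0642), the stricter filter (0.0643), only the groups compared (0.0603), the term for pairs of repeats (0.099) or without the 2 libraries with the fewest genes (0.0648). Cytosolic ribosomal proteins had 1 rise of 58, RPL3 with 0.23 (none adjusted over the list alone; adjusted p = 0.0449, adjusted p = 0.804 with an estimated correlation and adjusted p = 0.348 by fry). They did not pass with library size only (adjusted p = 0.282), the stricter filter (0.113) or only the groups compared (0.0623). SLC4A7 rose by 1.29 and SLC4A2 fell by 0.81.

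Under the naming rule the largest rises were WNK4 (2.81), the trafficking GTPase RAB3B (2.80), AOC3 (2.77), RPSAP52 (2.44), IL24 (2.40), OVGP1 (2.24), AOC2 (2.20) and KRTAP2-3 (2.08), where AOC2 and AOC3 are neighbouring paralogs. The largest falls under it were RAB17 (-2.15), AQP5 (-2.05), the RNA sensor TLR3 (-2.05), PRSS35 (-1.86), ALPP (-1.77), MYH15 (-1.73), MIR1915HG (-1.72) and RANBP3L (-1.72). Camera put 8 lists past the threshold, 6 up and 2 down, and fry 4. With an estimated correlation none passed, although 2 had an unadjusted p under 0.05. Within repeats 3 and 4 edgeR called no gene, where 3161 had an unadjusted p under 0.05 and DESeq2 called 368 higher and 207 lower. Within repeats 1 and 2 edgeR called 1051 higher and 855 lower. Ribosome biogenesis (adjusted p = 0.202) and interferon (0.118) did not pass within repeats 3 and 4, ribosomal proteins (0.239) did not within repeats 1 and 2, and the other lists passed in both. Inflammatory genes (adjusted p = 0.192), not past the threshold in the pooled fit, passed upward within repeats 3 and 4 (0.00408) and NRF2 targets (adjusted p = 0.08) upward within repeats 1 and 2 (0.00705). Ribosome biogenesis, interferon, ribosomal proteins and the endoplasmic reticulum chaperones also lost the threshold without single libraries, the chaperones without repeat 2 at pH 6.4 (adjusted p = 0.09), ribosome biogenesis without repeat 2 (0.0587) or 4 (0.0528) at pH 6.4, interferon without repeat 1 at pH 7.4 (0.0531), repeat 1 at pH 6.9 (0.132) or repeat 4 at pH 6.4 (0.135), and ribosomal proteins without any of 5 libraries (0.0531 to 0.194).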

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

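The tests of single libraries, of a wrong label, of a swap, of reads shared with pseudogenes and of other splits of the libraries were chosen only after the result was seen, while the tests of GC content and length, of low complexity behind the split of the repeats and of a mixture with pH 7.4 material were set down first.

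Single libraries were looked at by dividing the gap between an extreme library and its nearest neighbour by the range of its 4 libraries, over 323 groups that included 101 genes. A ratio above Dixon's critical value was reached in 12 groups, where chance alone gives about 1 in 20. The share of weakly expressed genes with a count of 0 was 22.2% in repeat 1 at pH 7.4 (ratio 0.993), against at most 0.153% in the other pH 7.4 libraries, and 0.75% in repeat 2 at pH 6.9 (ratio 1), against 0 in the others. In repeat 1 at pH 7.4 the nucleolar gene GNL3 was low at 119 CPM (ratio 0.86; the others 143 to 147), and the integrin ITGA5 was high at 210 CPM (ratio 0.911; the others 168 to 171). At pH 7.4, RPSAP52 reached 2.63 CPM in repeat 4 (ratio 0.877) and KLF9 11.2 CPM in repeat 2 (ratio 0.859). At pH 6.9, MVK reached 35.7 CPM in repeat 3 (ratio 0.831), PCK2 27.8 CPM in repeat 4 (ratio 0.844) and MYH15 58.6 CPM in repeat 1 (ratio 0.929), and SMAD3 was low at 196 CPM in repeat 4 (ratio 0.908). At pH 6.4, MAP2 reached 8.13 CPM in repeat 2 (ratio 0.96) and the carbonic anhydrase CA9 14.2 CPM in repeat 3 (ratio 0.832). Of the 12, 3 lay in repeat 1 at pH 7.4 and 2 in repeat 4 at pH 6.9, and no other library had more than 1.

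Repeat 1 at pH 7.4 lay far from all other libraries on the first principal component. A wrong label is argued against by its score of 0.014 on the axis from pH 7.4 to pH 6.4, below the lowest pH 6.9 score of 0.229. Low depth is argued against by 3 libraries that had fewer counts and more detected genes. Few distinct RNA molecules in the library may explain its place, since 22.2% of its weakly expressed genes had a count of 0 and at most 0.75% in any other library. No biological explanation was tested.

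On the third principal component the libraries of repeats 1 and 2 lay to 1 side of those of repeats 3 and 4 in every medium. Repeat 1 at pH 7.4 (-10.97) lay nearer to repeat 3 (-18.66) than to repeat 2 (28.64). At pH 6.4 the counts of repeats 3 and 4 differed more (chi-square per gene 53.6) than those of repeats 1 and 4 (42). In 1 fit over all media, RPL39 (-1.95), CSF2 (-1.65) and MMP1 (-1.61) were lower in repeats 3 and 4. MIF (2.03), UBE2S (2.27) and the pseudogene TMSB4XP8 (2.92) were higher there, on the log2 scale. These genes were picked after their values were seen, and no medium was tested alone for this split. After the trend of each library on GC content and length was removed, 2747 of the 3598 genes that had differed still did, among 3508 in all, which argues against that bias as the whole cause. Few distinct molecules in some libraries would leave few of the most abundant genes differing, but 37.7% of these 1733 genes did. This argues against low complexity as the whole cause. The 20.8% over all genes is no fair comparison, because abundant genes are called more readily. Reads shared with pseudogenes are argued against as the whole cause, because 76.4% of the genes that differed had no pseudogene copy by symbol. Genes that are pseudogenes themselves were counted here with those that have a copy. Genes with a copy were nevertheless over-represented, as 14425 of all 17334 genes examined had none. Such reads may contribute to the large differences, since genes with a copy or that are pseudogenes differed over 2-fold 5.59 times as often as others (7.63% of 2909 against 1.37% of 14425; Fisher's exact p = 3.51e-66). A gene and its pseudogene can share reads, so these genes are not independent and this p-value can overstate the evidence. A change of reagents or read length between the pairs stays open, the labels give no batch, and no biological explanation was tested.

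Repeat 3 at pH 6.4 lay between the media, with a score of 0.493. A swap with a pH 6.9 library is argued against, because the highest pH 6.9 score was 0.391 and the lowest of the other pH 6.4 libraries 0.894. A mixture with pH 7.4 material would dilute all changes alike. Across 552 genes, this library's share of the pH 6.4 change rose with the share reached at pH 6.9. The rho was 0.742, and the highest of 1000 shuffles gave 0.123. Both shares are fractions of the change from pH 7.4 to pH 6.4, and any values they have in common can raise rho. Shuffling genes removes that link, so 0.123 is not the rho expected under a mixture, and no conclusion is drawn. The median share of this library was 0.368 for genes that rose and 0.596 for genes that fell. A weaker exposure to acid and a mixture with pH 7.4 or pH 6.9 material stay open.

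Other splits of the same libraries were tried for each comparison fitted to its own 8 libraries. For pH 6.4 against pH 7.4, 1 of 35 splits, the real one with 4225 genes, gave as many, and the highest other gave 122. This is the smallest share that 35 splits allow, so chance is argued against but not excluded. For pH 6.4 against pH 6.9 the real split was again the only 1 of 35, with 2652 genes and 680 in the highest other, and the same holds. For pH 6.9 against pH 7.4, 2 of 35 splits gave as many as the real 250, and chance cannot be excluded at this number of splits. The other split put repeats 1 and 2 against repeats 3 and 4 and gave 2153 genes, several times the real count, which points to that structure of the libraries. These splits ignore the repeat numbers. In fits of all 12 libraries, 325 genes were higher and 289 lower at pH 6.9 with that split as a term, and 519 and 428 with the repeat number as a block. For any change among the 3 media, 1 of 100 drawn splits of the 12 libraries, the real one, gave as many as 4556 genes. Of the others 3 gave any gene, the highest 3900. Chance is argued against but not excluded, since another grouping came near the real count. For lists, 10 of 35 splits gave as many as the real 11 at pH 6.4 against pH 7.4 (highest other 13), 3 of 35 as many as the real 14 at pH 6.9 against pH 7.4 (highest other 16) and 22 of 35 as many as the real 6 at pH 6.4 against pH 6.9 (highest other 13). Chance can therefore not be excluded for the number of lists past camera's threshold in any comparison. For single lists, the number of the 35 splits with a camera p-value as small as the real one, itself included, was 1 at pH 6.4 against pH 7.4 for the stress response, fatty acid synthesis and MAPK, 2 for MondoA, 3 for cholesterol (lowest other 6.96e-30), 4 for mitosis, 7 for replication, 9 for heat shock, 15 for interferon and 19 for ribosomal proteins. At pH 6.9 against pH 7.4 it was 1 for the stress response, cholesterol, fatty acid synthesis, heat shock, MAPK, NRF2 and replication, 2 for mitosis, 6 for lysosome, 7 for ribosome biogenesis and 8 for hypoxia. At pH 6.4 against pH 6.9 it was 1 for MondoA, 2 for replication (lowest other 3.62e-20), 5 for MAPK, 14 for the stress response and chaperones, 16 for interferon and 18 for ribosomal proteins and for ribosome biogenesis.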

How the results depend on the processing

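The fits within pairs of repeats, with a term for those pairs and without selected libraries were tests chosen only after the result was seen. No called gene named in the text changed sign in any setting, but whether more genes were higher or lower did change. The settings reuse the libraries by which these genes were chosen, so a kept sign is no independent evidence. Lower genes outnumbered higher ones at pH 6.4 against pH 7.4 with library size only (2137 higher and 3159 lower), without repeat 1 at pH 7.4 and repeat 3 at pH 6.4 (3479 and 3561) and against a fold change of 1.5. They did so at pH 6.4 against pH 6.9 with library size only (1084 and 1756), without repeat 1 at pH 7.4 (1885 and 1952) and without that library and repeat 3 at pH 6.4. At pH 6.9 against pH 7.4 higher genes outnumbered lower ones with no filter (106 and 95), the term for pairs of repeats, the block with and without repeat 1 at pH 7.4, DESeq2 within repeats 1 and 2, and without repeat 3 at pH 6.4. In both acid media they did with no filter (95 and 85), the term and the block with and without that library. Counts are given as higher and lower genes, and the cause of a difference was not tested unless the setting leaves out libraries or genes by construction. At pH 6.4 against pH 7.4 the 2737 and 2584 genes became 821 and 707 within repeats 3 and 4 (1531 and 1195 with DESeq2), 1587 and 1385 at an adjusted p under 0.01, and 281 and 315 against a fold change of 1.5. At pH 6.9 against pH 7.4 the 55 and 72 genes became 106 higher without a filter, 275 and 284 with DESeq2, 111 and 139 with only the groups compared, 325 and 289 with the term for pairs of repeats, 2 and 5 within repeats 1 and 2 (168 and 143 with DESeq2), 0 and 0 within repeats 3 and 4 (52 and 69 with DESeq2), 6 and 14 without the libraries with the fewest genes (repeat 1 at pH 7.4 and repeat 2 at pH 6.9), 101 and 115 without repeat 1 at pH 7.4 and repeat 3 at pH 6.4, 11 and 22 at 0.01, and 0 and 4 against 1.5-fold (219 at an unadjusted p under 0.05). At pH 6.4 against pH 6.9 the 1550 and 1438 genes became 2520 and 2298 with the term, 855 lower within repeats 1 and 2, 0 and 0 within repeats 3 and 4 (368 and 207 with DESeq2), 2971 and 3215 without repeat 1 at pH 7.4 and repeat 3 at pH 6.4, 475 and 317 at 0.01, and 2 and 1 against 1.5-fold. The 4556 genes of any medium became 3005 and 298 within the pairs of repeats and 6854 without those libraries. The 52 and 69 genes of both acid media became 95 higher without a filter, 241 and 252 with DESeq2, 79 and 117 with only the groups compared, 295 and 266 with the term, 2 and 5 within repeats 1 and 2, 0 and 0 within repeats 3 and 4, 6 and 14 without the libraries with the fewest genes, 82 higher without repeat 1 at pH 7.4 and repeat 3 at pH 6.4, and means of 10.7 and 22.3 with split controls. Of the lists, 10, 11 and 8 past camera's threshold became 0, 2 and 0 with an estimated correlation and 12, 5 and 4 by fry. Other lists passed in some setting only. They were adhesion, apoptosis, chaperones, growth arrest, hypoxia, inflammation, lysosome, proton sensors and YAP at pH 6.4 against pH 7.4, adhesion, ribosomal proteins, inflammation, interferon, mitochondrial mRNAs, MondoA, histones and water regulation at pH 6.9 against pH 7.4, and cholesterol, fatty acid synthesis, growth arrest, inflammation, NRF2 and proton sensors at pH 6.4 against pH 6.9. The repeat numbers gave pairs of libraries whose deviations correlated with r from 0.0798 to 0.47, 11 of 12 over 0.1. Of the 12 libraries 10 matched their own number best. The labels number the repeats 1 to 4 in each medium but state no pairing, so a pairing is a hint from these data. With the number as a replicate block the counts were 3751 and 3539, 519 and 428, and 2823 and 2633, with 7012 for any medium and 472 and 395 in both acid media. With the block and without repeat 1 at pH 7.4 they were 364 and 310 at pH 6.9 against pH 7.4, 3413 and 3399 at pH 6.4 against pH 6.9, 7719 for any medium and 345 and 300 in both. The block lost 0 named calls in the 3 comparisons and gained 2, 28 and 3. With each library left out, pH 6.4 against pH 7.4 gave 2005 to 3256 higher and 1790 to 3155 lower genes, pH 6.9 against pH 7.4 gave 12 to 154 and 27 to 152, pH 6.4 against pH 6.9 gave 659 to 2474 and 512 to 2470, any medium 2775 to 5997, both acid media 12 to 112 and 27 to 126, and lists 10 to 14, 10 to 14 and 6 to 9. Libraries that moved a count by over 1.5 times follow. At pH 6.9 against pH 7.4 the higher genes became 33, 12 and 32 without repeats 1, 3 and 4 at pH 7.4, 28, 16, 34 and 21 without repeats 1 to 4 at pH 6.9, and 34 and 154 without repeats 1 and 3 at pH 6.4. The lower genes became 42, 42, 27 and 44 without repeats 1 to 4 at pH 7.4, 38, 32, 40 and 32 without those at pH 6.9, and 152 without repeat 3 at pH 6.4. At pH 6.4 against pH 6.9 the counts became 659 and 512, 2474 and 2470, and 685 and 546 without repeats 2, 3 and 4 at pH 6.4, and 848 and 722, 816 and 812, and 958 and 922 without repeats 1, 3 and 4 at pH 6.9. Any medium gave 2775 and 2826 without repeats 2 and 4 at pH 6.4. The higher genes of both acid media became 33, 12 and 32 without repeats 1, 3 and 4 at pH 7.4, 28, 16, 33 and 21 without repeats 1 to 4 at pH 6.9, and 34 and 112 without repeats 1 and 3 at pH 6.4. Their lower genes became 41, 41, 27 and 43 without repeats 1 to 4 at pH 7.4, 38, 32, 40 and 32 without those at pH 6.9, and 126 without repeat 3 at pH 6.4. Named calls kept in every such run were 127 of 130, 17 of 37 and 89 of 127, and lists 7 of 10, 9 of 11 and 4 of 8. RPS16, RPL7A and ERN1 lost their call at pH 6.4 against pH 7.4. The fit of only the groups compared was not run for any medium, DESeq2 not for lists, and DESeq2's count for any medium came from its likelihood ratio test.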

Other observations

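The tests of NFAT5 targets and of histone genes below, and the rules for reading them, were chosen only after the result was seen.

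Single genes changed at pH 6.4 within lists that did not pass in the pooled fit. Among inflammatory genes the cytokine IL24 and the regulators RELB and NFKBIZ were higher by 2.75, 0.90 and 0.86 on the log2 scale and NFKBIA, which restrains NF-kB, fell by 0.99, while of the list of 32 genes 10 rose and 3 fell (adjusted p = 0.0553, and 0.000157 within repeats 3 and 4). IL1A rose by 3.98 but stayed at a mean of 1.56 CPM. In the lysosome, the kinase ULK1, which starts autophagy, and the sterol exporter NPC1 rose by 0.83 and 0.89, while the sialidase NEU1 fell by 0.65. Among regulators of fat burning PPARGC1A fell 6.60-fold and PPARA rose by 1.21.

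Some genes that changed at pH 6.9 gave no call between the acid media. RELN had 8.12 ± 1.68 CPM at pH 7.4, 3.30 ± 0.907 at pH 6.9 and 4.93 ± 1.58 at pH 6.4 (SD, n = 4), and the difference between the acid media was not called (log2 0.57, adjusted p = 0.14). SC5D fell by 0.84 at pH 6.9 and by 0.78 at pH 6.4, with 0.06 between them. CHAC1, PSAT1 and PCK2 likewise gave 0.12, -0.22 and -0.21 between pH 6.4 and pH 6.9, whereas TXNIP and KLF9 rose by 1.89 and 1.15 between them. PKM, among the most abundant transcripts at 3754 CPM, gave 3130 at pH 6.9 and 2525 at pH 6.4.

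AKR1B1 and SLC5A3, which build up organic osmolytes, fell at pH 6.9 and pH 6.4 and SLC6A6 rose at pH 6.4, and lower activity of the tonicity factor NFAT5 may lie behind the falls. A list of 15 NFAT5 targets, written after these 3 genes were seen, was lower at pH 6.4 than at pH 7.4 by camera (p = 0.00146, and 0.00789 with an estimated correlation; 6 fell and 1 rose), but it holds the genes that prompted it and decides nothing. The 12 other targets gave p = 0.0356 by camera with the preset and 0.054 with an estimated correlation. They are no independent test, as they include NFAT5 itself, and S100A4, AQP1 and CCL2 belong to lists of the main analysis. Among them S100A4, AQP1, SLC6A12 and CCL2 fell, the other 8 were not called, and the mean of -0.51 stood against a median of -0.12. NFAT5 itself gave 0.14 (adjusted p = 0.347), so the idea stays open.

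At pH 6.4 against pH 7.4, 24 of 40 replication genes fell and 25 of 40 mitosis genes rose, with 1 in each list going the other way, and neither list passed with an estimated correlation (adjusted p = 0.713 and adjusted p = 0.451). Fewer cells in S phase could give such a pattern. Replication-dependent histone genes, made in S phase, would then fall with the replication genes. Between pH 6.4 and pH 6.9 the histone list had a mean of -0.01 and the replication list -0.62, a difference of 0.61 (SE 0.17), and the histone list did not pass camera (adjusted p = 0.676). No conclusion is drawn from these values, because 16 of 44 histone genes were tested, under the 80% required. Poly(A) selection also measures these mRNAs poorly because most lack a poly(A) tail. The test is therefore void and the idea stays open.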
